A study of Mus musculus with 10 samples.

How the data were processed

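RNA of mouse primary hippocampal neurons was measured in 10 libraries, 2 treated with scramble RNA and 4 with each anti-miR, from day 10 to day 12 in vitro. Per the labels' protocols, the RNA was polyadenylated, the libraries were made with the TruSeq RNA kit v2 and reads were single-end and 50 bp long from a HiSeq2000. Per the submitters' processing notes, FastQC 0.11.5, STAR 2.5.2b, featureCounts and Subread 1.5.1 were used with genome build mm10. The notes state neither the annotation release nor the strand setting nor the treatment of reads that map to several places, and the kit does not mark strand. The deposited counts are raw counts per Ensembl gene, 1 table per library, and carry no normalization, as their whole numbers and unequal totals show. The authors also deposited a comparison table for each anti-miR against control, with log2 fold changes, per the file headers. The p-value and adjusted p-value columns deposited by the authors have header names of DESeq2's result table, but the tool, model and covariates are not stated. The normalized signal columns that the authors deposited per library in these tables equal the raw counts divided by a single factor per library, with a relative spread of at most 1.1e-09. These tables held 17645 and 17722 genes, with no adjusted p for 5137 and 4123 of them, and were used for a comparison of calls alone. All columns could be assigned to a library.

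Everything else was computed from the raw counts with R 4.3.3. Genes were matched to symbols by Ensembl identifier (48349 of 48709), and coordinates and transcript sequences came from the mm10 reference. Low counts were removed with edgeR's filterByExpr, leaving 16884 genes, and libraries were scaled by TMM. Each comparison was tested with edgeR 4.0.16 (quasi-likelihood, robust, prior count of 2 for log2 CPM), two-sided, in a fit of all 10 libraries with 3 groups and no covariate, at a Benjamini-Hochberg adjusted p of 0.05. All libraries shared the estimate of spread because control has 2 libraries. The comparisons were each anti-miR against control and the anti-miRs against each other. The p-values measure the spread between these libraries, since nothing in the labels says that the libraries of a group came from separate cultures.

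Before the data were examined, 28 gene lists, the tests, the alternatives and the rule for named genes were fixed. The lists were pan-neuronal, excitatory and inhibitory neuron markers, glutamate receptors and postsynaptic density, presynaptic vesicle and release, GABA receptors and inhibitory postsynapse, activity-regulated genes, voltage-gated ion channels, dendrite, axon and cytoskeleton, mitochondrially encoded genes, nuclear oxidative phosphorylation, cytosolic ribosomal proteins, integrated stress and unfolded protein response, interferon response, inflammatory and NF-kB response, p53 targets, cholesterol synthesis, lysosome and autophagy, NRF2 response, glycolysis and hypoxia, markers of astrocytes, microglia and macrophages, oligodendrocyte lineage, endothelial, mural and fibroblast cells and proliferating progenitors, microRNA machinery, host transcripts, and nuclear-retained noncoding transcripts. Some genes stand in more than a single list, such as Meg3, Rian and Mirg in the last pair. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 (at least 5 tested members, adjusted over the 28 lists), and also with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance and compares them with no other genes. The named-gene rule took, per comparison against control, the 12 largest rises and 12 largest falls among genes past the threshold with a symbol, a mean log2 CPM of at least 1 and every treated library on the same side of both controls. For the direct comparison it took 8 in each direction or, with none past the threshold, the 5 of smallest p. It further took up to 4 members of smallest p per list, Mirg, Rian, Meg3 and Clcn5, up to 5 called risers with a seed site per anti-miR and up to 6 genes called alike against control. Genes outside the rule are named as such where they appear, and some genes that the rule took are not reported here.

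Seed sites were searched in the longest annotated 3' UTR of each gene as GGTAACC, GTAACCA or GGTAACCA for miR-409-5p and GGTGCAT, GTGCATA or GGTGCATA for miR-501-3p, and compared with 100 heptamers holding the seed's bases in another order. The trend on GC content and length was removed by fitting, in each library, the log2 deviation of each gene on splines (5 degrees of freedom) of its transcript's GC content and log length and entering the fit as an offset, and 99.7% of tested genes had these values. The trend was fitted on genes with a mean log2 CPM above 1 and applied to all genes with these values. This correction was chosen after the data were seen, and it may also remove differences that belong to the cells or bring in others. Mitochondrial shares carry exact Clopper-Pearson 95% intervals, which cover counting error alone, as does the limit of 3 counts for a count of 0, because reads amplified by PCR without molecular identifiers are not independent molecules. Group differences of library measures were tested by exact permutation. Mitochondrial tRNAs, the antisense genes Gt(ROSA)26Sor and Gm16185, the sense-intronic Gm43031, the pseudogenes Gm28438 and Gm10263 and Gm47283, which has a near copy, are uncertain, as their reads may belong to overlapping or similar genes.

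Replicate numbers are shared between groups in the labels, but no label says what a number marks. The deviations of same-numbered libraries of the anti-miR groups from their group means, over 12832 genes with a mean log2 CPM above 1, correlated at 0.375, 0.164, 0.121 and 0.306 for numbers 1 to 4. All 4 values exceed 0.1, so these groups were treated as paired from the data. The decision rests on that choice of genes, as the values over all 16884 tested genes were 0.174, 0.0893, 0.0639 and 0.149, with numbers 2 and 3 below 0.1. With GC and length corrected, they were 0.172, 0.197, 0.0814 and 0.192 over the 12832 genes, with number 3 below 0.1. For these groups, fits with the number as a block are given beside results they change. Those fits held all 10 libraries, with the control libraries in the blocks of their numbers. Pairing with control, which has 2 numbers, was not established.

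Alternatives were RLE, upper-quartile and total-count scaling, no filter, a stricter filter, DESeq2 1.42.0, limma's voom with sample weights, a fit of the compared groups alone, the replicate block, a surrogate variable (sva 3.50.0), each library left out in turn, and GC and length correction with and without the block. Library pairs within groups were compared by chi-square over genes, and the statistic per degree of freedom ran from 1.59 to 10.9, so no pair of count tables within a group held the same library. Pairs between groups were not compared.

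The gene test, camera and the GC and length correction were tested on simulated counts drawn from the real means and depths, and the other procedures were not. In the simulated comparison of anti-miR-409-5p with control (16870 genes), 31.3%, 70.1% and 78.8% of genes changed 1.2-fold, 1.5-fold and 2-fold were called, with 7.69% of 130 calls false. For the comparison between anti-miRs the shares were 38.8%, 80.6% and 92.4%, with 8.44% of 154 calls false, and with no change simulated for anti-miR-501-3p against control there was 1 call. A simulated GC trend (16872 genes) gave 1969 calls, 93.3% of them false, and 141 calls, 7.80% false, after the correction. That trend was linear in GC content, with no effect of length, and the changed genes were drawn without regard to GC content. It does not show how the correction acts where true changes follow GC content. A simulated shifted list had a camera adjusted p of 1.4e-29 with a preset correlation (2.3e-04 with an estimated correlation), and 0 other lists were called. The simulated genes were drawn independently and without a GC trend here. The list simulation therefore does not show how camera acts on genes that move together.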

Results

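Polyadenylated RNA was sequenced from mouse hippocampal neurons grown in primary culture. The neurons took up lipid nanoparticles on day 10 in vitro and were harvested 48 h later. The nanoparticles carried scramble RNA (control, n = 2 libraries), an antisense inhibitor of microRNA-409-5p (anti-miR-409-5p, n = 4) or one of microRNA-501-3p (anti-miR-501-3p, n = 4). The series asks what silencing of these microRNAs, described there as induced by exercise, does to neuronal homeostasis. Total gene counts were 27288613 and 29317799 in control replicates 1 and 2, 26631121, 31480739, 22254788 and 32096808 in anti-miR-409-5p replicates 1 to 4, and 28751713, 29813333, 26441569 and 29871556 in anti-miR-501-3p replicates 1 to 4. Of 48709 genes in the count tables, 16884 had enough counts to be tested.

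Transcripts of the mitochondrial genome took a larger share of the counts under both anti-miRs than in control. The share was 2.59% (95% exact Clopper-Pearson interval 2.584 to 2.596) and 2.78% (2.770 to 2.782) in the control libraries. Anti-miR-409-5p replicates 1 to 4 held 3.397% (3.390 to 3.404), 3.639% (3.633 to 3.646), 3.670% (3.662 to 3.678) and 3.804% (3.798 to 3.811). Anti-miR-501-3p replicates 1 to 4 held 3.327% (3.320 to 3.333), 3.689% (3.683 to 3.696), 3.808% (3.801 to 3.816) and 3.953% (3.946 to 3.960). The group means were 2.68% ± 0.132 (SD, n = 2), 3.63% ± 0.170 (n = 4) and 3.69% ± 0.268 (n = 4). All 8 anti-miR libraries together exceeded control by 0.978 percentage points (two-sided exact permutation test over 45 splits, p = 0.0222, the smallest possible). Each anti-miR alone exceeded control by 0.945 and 1.01 points, where 15 splits allow no exact p below the observed 0.0667. The anti-miRs differed by -0.0667 points (exact permutation p = 0.686 over 70 splits). The libraries also differed in how counts followed the GC content of the transcripts. The slope of log2 counts, as deviation from the mean over libraries, per 10 points of GC was 0.238 ± 0.0489 (SD, n = 2) in control, -0.0428 ± 0.0699 (n = 4) under anti-miR-409-5p and -0.0760 ± 0.0590 (n = 4) under anti-miR-501-3p. Genes with a mean log2 CPM above 1 entered these slopes. The anti-miR libraries differed from control by -0.297 in this slope (exact permutation p = 0.0222, 45 splits), and the anti-miRs differed by 0.0331 (exact permutation p = 0.457, 70 splits). The labels give no preparation batch or date, so no value within batches could be computed.

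**Figure D1:**
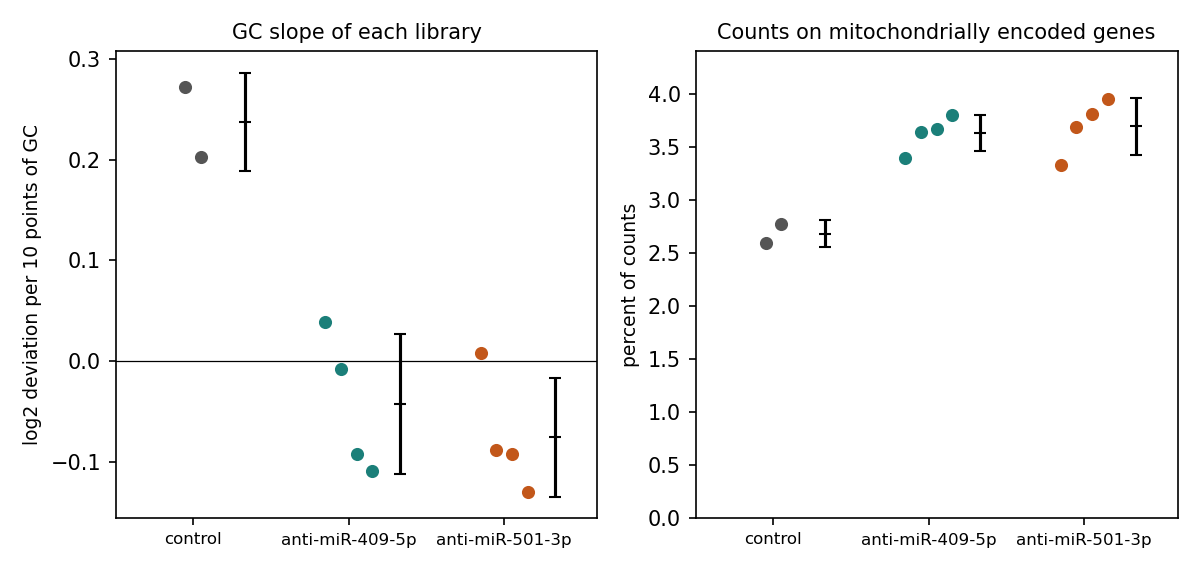
GC slope (left, log2 deviation per 10 points of transcript GC content) and percent of counts on mitochondrially encoded genes (right) for each of 10 libraries, points within a group in order of replicate number, with the group mean and SD beside them. Both control libraries lie apart from all 8 anti-miR libraries in both measures (control mean slope 0.238 and mean share 2.68%).

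The genes of the targeted microRNAs gave no counts, while transcripts from their host regions were measured. Mir409 (mm10 chromosome 12, 109743158 to 109743236) and Mir501 (chromosome X, 7241243 to 7241351) had 0 counts in all 10 libraries, which allows at most 0.0935 to 0.135 CPM (counts scaled to a common depth) per library at 3 counts. Poly(A) libraries do not measure mature microRNAs, so the loss of either microRNA could not be checked. Rian, a noncoding RNA of the imprinted Dlk1-Dio3 region on chromosome 12 (109603940 to 109661716), rose under both anti-miRs, from 541 ± 22.0 CPM (SD, n = 2) to 648 ± 24.7 (n = 4) and 659 ± 34.0 (n = 4). Its log2 fold changes were 0.26 ± 0.05 (SE) and 0.28 ± 0.05 (edgeR adjusted p = 8.3e-04 and 2.8e-04). Mirg, the noncoding transcript that spans Mir409 (chromosome 12, 109729764 to 109749460), had log2 fold changes of 0.087 ± 0.07 and 0.053 ± 0.07 (edgeR adjusted p = 0.352 and 0.583). Its neighbour Meg3 (109541001 to 109571726) had 0.23 ± 0.10 and 0.25 ± 0.10 (edgeR adjusted p = 0.115 and 0.0784), but without anti-miR-501-3p replicate 1 these were 0.24 and 0.33 and passed (edgeR adjusted p = 0.0015 and 1.2e-04). Clcn5, the chloride transporter gene that hosts Mir501 (chromosome X, 7153810 to 7319358), rose under anti-miR-501-3p with a log2 fold change of 0.19 ± 0.05 (edgeR adjusted p = 0.010) and had 0.095 ± 0.05 under anti-miR-409-5p (edgeR adjusted p = 0.199). The difference between the anti-miRs for Clcn5 was -0.098 ± 0.04 (edgeR adjusted p = 0.845). The Clcn5 call under anti-miR-501-3p ended without control 1 (edgeR adjusted p = 0.232), and the gene passed under anti-miR-409-5p without control 2 (edgeR adjusted p = 0.0337). After removal of the trend on GC content and length, the log2 fold change of Rian was -0.43 and -0.51 (edgeR adjusted p = 0.036 and 0.013) and that of Clcn5 under anti-miR-501-3p was 0.027.

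The comparison of anti-miR-409-5p with control asked which transcripts move when miR-409-5p is silenced. Counts on mitochondrial tRNA genes and on a set of protein-coding genes were higher. Those on the mitochondrial alanine tRNA gene mt-Ta (mm10 chromosome M, 5018 to 5086) rose 6.20-fold, from 2.51 ± 0.181 CPM (SD, n = 2) to 15.6 ± 2.98 (n = 4). Those on the cysteine tRNA gene mt-Tc (5192 to 5257) rose 3.86-fold, from 3.02 ± 0.0122 to 11.6 ± 0.976 CPM. Reads at these tRNA genes may belong to overlapping transcripts, so a rise of the tRNAs themselves is not shown. Lypla1, which encodes an enzyme that removes palmitate from proteins (chromosome 1, 4807788 to 4848410), rose 2.82-fold to 21.2 ± 6.27 CPM, and Zxdb, a zinc finger gene (chromosome X, 94724569 to 94730187), rose 2.76-fold to 7.53 ± 1.31 CPM. Lpin3, a phosphatidate phosphatase gene of lipid synthesis (chromosome 2, 160880670 to 160906002), had 0.540 times the control level, 1.89 ± 0.326 against 3.52 ± 0.156 CPM, and Mapkapk3, a kinase gene downstream of p38 (chromosome 9, 107254927 to 107289877), had 0.654 times.

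In edgeR's quasi-likelihood test, 4696 genes passed at a Benjamini-Hochberg adjusted p of 0.05, 2634 higher and 2062 lower under anti-miR-409-5p, and 6610 had an unadjusted p under 0.05. Of the called genes, 4430 were protein-coding and 111 changed more than 2-fold, 96 of them upward, while the median absolute log2 fold change was 0.25 with a median SE of 0.06. With a surrogate variable edgeR called 831 genes, 743 higher and 88 lower, and among the genes above Lypla1, Lpin3 and Mapkapk3 ended. Upper-quartile scaling gave 2233 higher and 3074 lower genes, and scaling by total counts gave 2193 and 3209. The log2 fold changes were 2.63 ± 0.23 (SE) for mt-Ta, 1.95 ± 0.12 for mt-Tc, 1.498 ± 0.31 for Lypla1, 1.46 ± 0.21 for Zxdb, -0.89 ± 0.17 for Lpin3 and -0.61 ± 0.15 for Mapkapk3 (edgeR adjusted p = 4.9e-05, 7.2e-08, 0.0104, 3.4e-04, 0.00114 and 0.0063). Further large rises were Gm17066 (2.03), Gm38393 (1.47), Gt(ROSA)26Sor (1.44), Gm16185 (1.41), Gm28438 (1.40), Gm43031 (1.33), the zinc finger gene Zfp758 (1.28) and Gm26617 (1.27), given as log2 fold changes. Further falls were Adamts14 (-0.67), Trim47 (-0.61), Gm47283 (-0.60), Gm10263 (-0.58), Trim21 (-0.57), Ppp1r35 (-0.54), Ccdc88b (-0.54), Bola1 (-0.54), Endog (-0.52) and Cilp2 (-0.51). All 24 genes lay on the same side of both control libraries in all 4 anti-miR-409-5p libraries. Of the 12 rises, 4 ended without control 1 (Lypla1 0.102, Gm38393 0.171, Gt(ROSA)26Sor 0.133 and Gm26617 0.213, as edgeR adjusted p), and the same 4 without control 2 (0.0558, 0.0827, 0.0695 and 0.0814), with Gm38393 (0.0515) and Gm26617 (0.0576) also ending without anti-miR-409-5p replicate 3. Of the 12 falls, 9 ended without control 1 (Adamts14 0.103, Mapkapk3 0.113, Gm47283 0.226, Gm10263 0.212, Trim21 0.0651, Ppp1r35 0.196, Bola1 0.0560, Endog 0.154, Cilp2 0.394) and 4 without control 2 (Trim47 0.0504, Gm10263 0.0770, Trim21 0.127, Ccdc88b 0.348), as edgeR adjusted p. Gm10263 also ended without anti-miR-409-5p replicate 3 (edgeR adjusted p = 0.0642) or 4 (0.0593), and Cilp2 without replicate 3 (0.0582).

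Fold changes followed transcript GC content. The Spearman correlation across genes, which are not independent replicates, was -0.709 for anti-miR-409-5p, and the median GC content was 42.6% for genes that rose, 57.0% for genes that fell and 49.8% for all tested genes. Once the trend on GC content and length was removed from each library, edgeR called 894 genes (534 higher, 360 lower), and 546 of the original calls (11.6%) kept their direction and passed. A further 58 of the original calls passed in the opposite direction. Among the largest rises mt-Ta, Gm17066, Zxdb, Gm16185, Gm43031 and Zfp758 still passed. Their corrected log2 fold changes were 1.44, 1.204, 1.47, 0.56, 0.49 and 0.59, in this order. All but that of Zxdb were smaller than before the correction. Of the falls, Lpin3, Trim21, Bola1 and Mapkapk3 passed (-0.76, -0.67, -0.32 and -0.496 corrected). The rises of mt-Tc (log2 fold change 1.00, edgeR adjusted p = 0.16) and Lypla1 (0.99, 0.057) did not pass. Without control 1 the count was 1302, 1132 of them higher, with the remaining control library assumed to vary like the other groups.

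**Figure D2:**
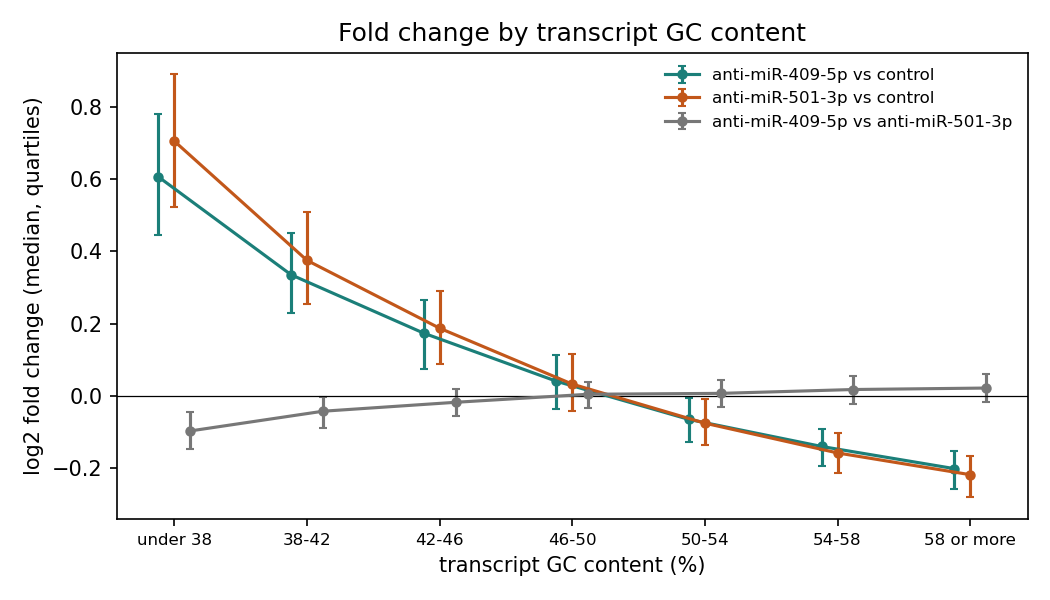
Median log2 fold change with quartiles (vertical axis) of 12811 tested genes with a mean log2 CPM above 1, grouped by transcript GC content in percent (horizontal axis), for the 3 comparisons. Against control the medians run from 0.61 and 0.71 in the 225 genes under 38% to -0.20 and -0.22 in the 1410 genes at 58% or more, while between the anti-miRs they run from -0.097 to 0.021.

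Grouped by function, 8 of 28 lists passed camera with a preset correlation under anti-miR-409-5p and 0 with an estimated correlation, so their called members are given and no change of a group is claimed. Of 77 nuclear genes of oxidative phosphorylation, 44 fell and 1 rose, or 47 and 1 adjusted over the list alone, with a median log2 fold change of -0.18. Cox6b1 (-0.24), Ndufa6 (-0.26) and Atp5j2 (-0.24), subunits of respiratory complexes and ATP synthase, fell, and the riser was cytochrome c, Cycs (0.75). Of 9 tested mitochondrially encoded genes, 8 rose (9 adjusted over the list alone), with a median of 0.63, as for mt-Nd1 (0.73), the ribosomal RNA mt-Rnr2 (0.68) and mt-Co1 (0.30). Of 78 cytosolic ribosomal protein genes, 24 fell, among them Rps15 (-0.25) and Rplp0 (-0.22), and Rpl15 (0.51) rose (28 and 1 adjusted over the list alone), with a median of -0.16. The glycolysis and hypoxia list had 13 falls and 1 rise among 30 genes, the same counts adjusted over the list alone, and a median of -0.16. The glycolytic enzyme genes Aldoa (-0.24), Tpi1 (-0.22) and Hk1 (-0.18) fell and the mitophagy receptor gene Bnip3l (0.36) rose. Genes of GABA receptors and the inhibitory postsynapse rose in 12 of 20 cases and fell in 2 (14 and 3 adjusted over the list alone), with a median of 0.23, including the receptor subunit Gabra4 (0.46) and the chloride importer Slc12a2 (0.39). Nuclear-retained noncoding transcripts rose in 6 of 15 cases, also adjusted over the list alone, with a median of 0.23, including Snhg14 (1.12) and A330008L17Rik (0.93). In the lysosome and autophagy list, 12 of 40 genes fell and 4 rose (16 and 4 adjusted over the list alone; median -0.10), with Lamp2 (0.37) up and Gaa (-0.25) and Sqstm1 (-0.18) down. In the integrated stress and unfolded protein response list, 10 of 37 fell and 3 rose (13 and 4 adjusted over the list alone; median -0.082), with Dnajb9 (0.53) up and the transcription factors Atf4 (-0.18) and Ddit3 (-0.24) down.

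These 8 of 28 lists passed limma's camera with a preset correlation between genes. The adjusted p was 2.3e-09 for oxidative phosphorylation, 2.0e-06 for mitochondrially encoded genes, 1.3e-04 for ribosomal proteins, 1.4e-04 for glycolysis and hypoxia, 0.0011 for GABA receptors, 0.0074 for lysosome and autophagy, 0.0132 for nuclear-retained transcripts and 0.0459 for the stress response. None of these calls held in camera with an estimated correlation, where the adjusted p was 0.631 for lysosome and autophagy, 0.579 for glycolysis and hypoxia and 0.558 for the other 6 lists. After GC and length correction, oxidative phosphorylation (median -0.068, camera adjusted p = 5.7e-06) and glycolysis and hypoxia (-0.081, 0.0010) passed, and the other 6 did not, while with an estimated correlation none passed (smallest camera adjusted p = 0.656). The stress response call ended in camera without control 2 (adjusted p = 0.0898), anti-miR-409-5p replicate 1 (0.0512), 2 (0.0936) or 4 (0.0517) or anti-miR-501-3p replicate 4 (0.0611). Single members lost their call in edgeR without control 1, namely Atp5j2 (adjusted p = 0.0523), Rps15 and Rplp0 (0.0929), Sqstm1 (0.122), Dnajb9 (0.0769), Atf4 (0.172), Ddit3 (0.0975), A330008L17Rik (0.0675) and Snhg14 (0.183). Without control 2, Ddit3 (edgeR adjusted p = 0.0761) and Snhg14 (0.0910) ended, and Snhg14 also ended without anti-miR-409-5p replicate 3 (0.0582) or 4 (0.0512).

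**Figure D3:**
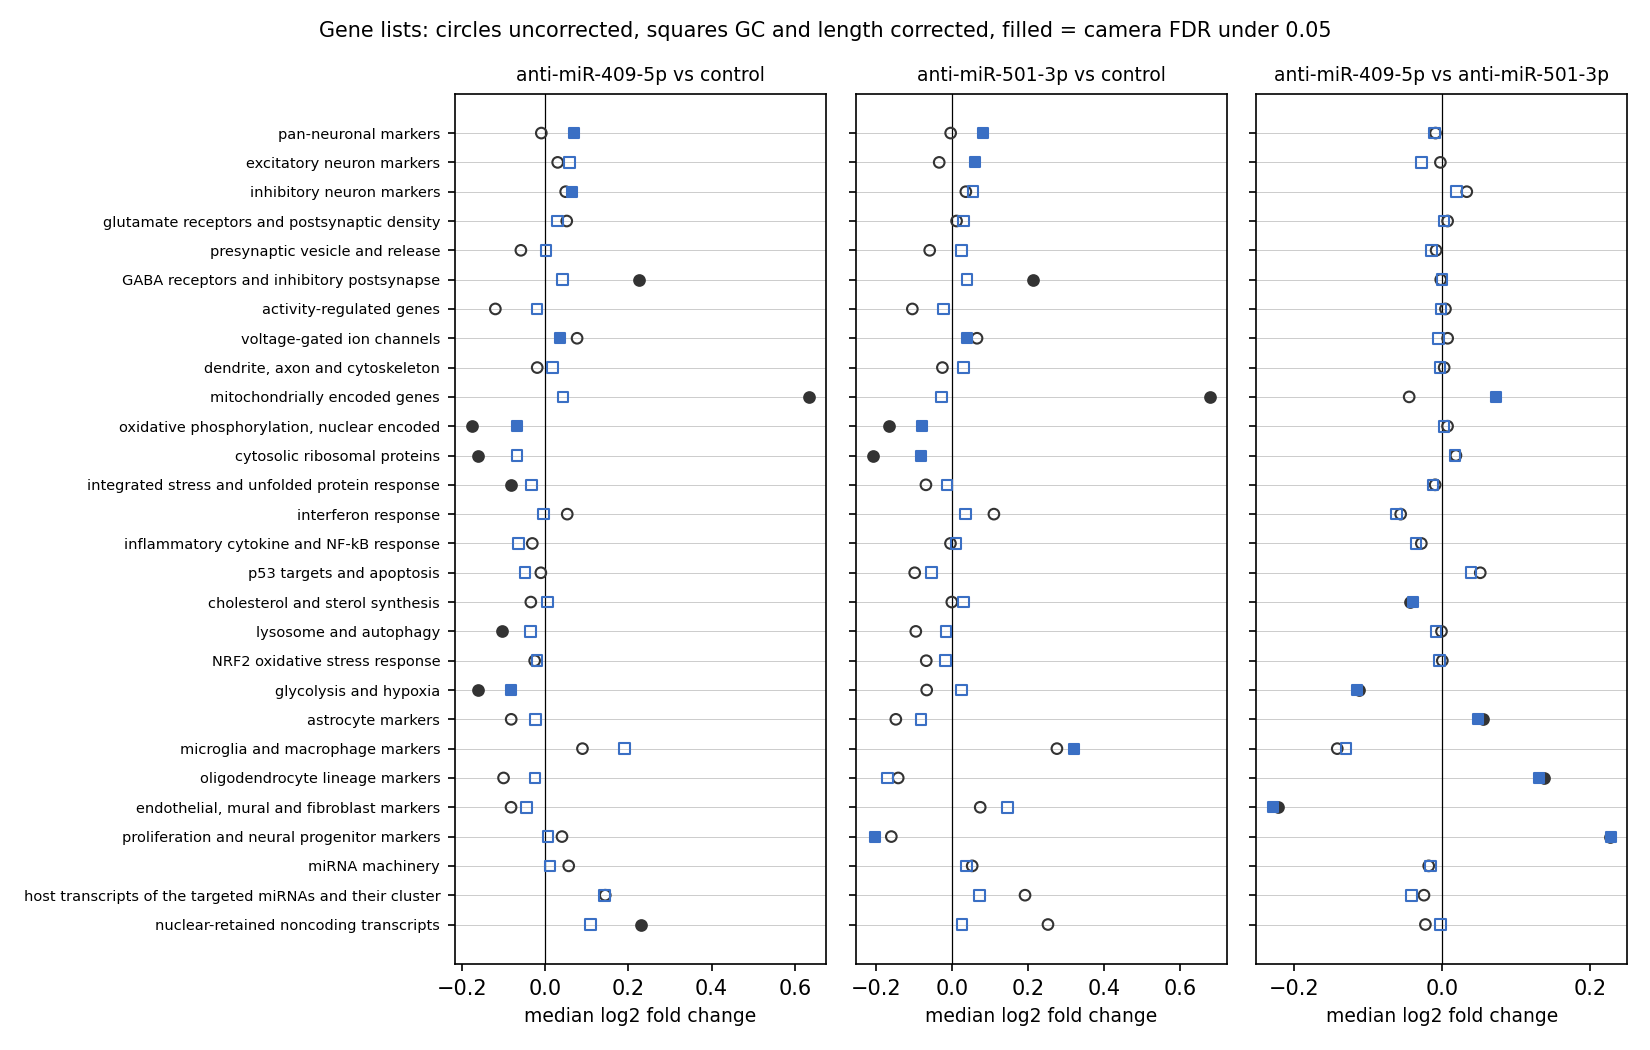
Median log2 fold change (horizontal axis) of 28 gene lists in the 3 comparisons, before (circles) and after (squares) correction for transcript GC content and length, with filled symbols where camera's adjusted p was under 0.05. Nuclear oxidative phosphorylation genes lie below 0 against control in both settings, whereas the medians of mitochondrially encoded genes drop from 0.63 and 0.68 to 0.043 and -0.027.

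The comparison of anti-miR-501-3p with control asked the same of miR-501-3p. Counts on the mitochondrial tRNA gene mt-Ta rose 6.50-fold to 16.4 ± 1.96 CPM (SD, n = 4) and those on mt-Tc 3.85-fold to 11.6 ± 1.18 CPM. Here too the reads may belong to overlapping transcripts. Ikzf5, a zinc finger transcription factor of the Ikaros family (mm10 chromosome 7, 131388652 to 131410521), rose 4.38-fold, from 0.770 ± 0.234 (n = 2) to 3.40 ± 0.766 CPM (n = 4), Lypla1 3.40-fold to 25.5 ± 2.74 CPM and Zxdb 3.36-fold to 9.15 ± 1.38 CPM. Scand1 (chromosome 2, 156311847 to 156312704) had 0.567 times the control level, 9.65 ± 2.95 against 17.05 ± 0.441 CPM, and Mapkapk3 had 0.599 times. Cdt1, which licenses DNA replication, Prr7, a proline-rich protein of the postsynaptic density, and the potassium channel gene Kcnk12 also fell.

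In edgeR's quasi-likelihood test, 5579 genes passed at an adjusted p of 0.05, 2974 higher and 2605 lower under anti-miR-501-3p, and 7195 had an unadjusted p under 0.05. Of the called genes, 5224 were protein-coding and 184 changed more than 2-fold, 164 of them upward, with a median absolute log2 fold change of 0.26 and a median SE of 0.06. With a surrogate variable edgeR called 592 genes, 567 higher and 25 lower, and among the genes above Ikzf5, Lypla1, Scand1, Mapkapk3, Cdt1, Prr7 and Kcnk12 ended. Upper-quartile scaling gave 2540 higher and 3607 lower genes, and scaling by total counts gave 2452 and 3779. The log2 fold changes were 2.70 ± 0.23 (SE) for mt-Ta, 1.94 ± 0.12 for mt-Tc, 2.13 ± 0.52 for Ikzf5, 1.77 ± 0.31 for Lypla1, 1.75 ± 0.20 for Zxdb, -0.82 ± 0.24 for Scand1 and -0.74 ± 0.15 for Mapkapk3 (edgeR adjusted p = 2.1e-05, 7.4e-08, 0.0125, 0.0038, 5.4e-05, 0.0306 and 0.0014). Other large rises were Gm17066 (2.25), Gm38393 (1.80), Gt(ROSA)26Sor (1.77), Gm38104 (1.58), Gm16185 (1.57), Gm28438 (1.51) and Gm43031 (1.45). Other falls were Gm47283 (-0.72), Gm10263 (-0.68), Cdt1 (-0.67), Kcnk12 (-0.66), Inava (-0.65), Lpin3 (-0.65), Prr7 (-0.64), Gtse1 (-0.62), C1qtnf4 (-0.61) and Phf21b (-0.61). All 24 genes lay on the same side of both control libraries in all 4 anti-miR-501-3p libraries, and Lypla1 in replicate 1 (4.43 log2 CPM) lay below the other libraries of that group (4.73 to 4.78), toward control. Without control 1, edgeR's adjusted p ended the calls of Ikzf5 (0.131), Gm38393 (0.0919), Gt(ROSA)26Sor (0.0625) and Lypla1 (0.0547) among the rises and of Scand1 (0.179), Gm47283 (0.115), Gm10263 (0.121), Cdt1 (0.0917), Inava (0.156), Lpin3 (0.0869), Prr7 (0.132), Gtse1 (0.152), C1qtnf4 (0.0716) and Phf21b (0.177) among the falls. Ikzf5 (edgeR adjusted p = 0.0517) and Scand1 (0.104) also ended without control 2, and Scand1 without anti-miR-409-5p replicate 1 (0.0541) or anti-miR-501-3p replicate 3 (0.0567).

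Across genes, which are not independent replicates, the Spearman correlation of fold change with GC content was -0.713, and the median GC content was 42.6% for genes that rose and 56.8% for genes that fell. After removal of the trend on GC content and length, edgeR called 1349 genes (782 higher, 567 lower), and 844 of the original calls (15.1%) kept their direction and passed. A further 110 of the original calls passed in the opposite direction. Of the named rises, mt-Ta, Gm17066, Gt(ROSA)26Sor, Lypla1, Zxdb, Gm16185 and Gm43031 still passed, with corrected log2 fold changes of 1.55, 1.25, 1.18, 1.19, 1.77, 0.58 and 0.45. Of the falls, Mapkapk3, Gm10263, Cdt1, Lpin3, Prr7, Gtse1 and Phf21b passed (-0.61, -0.59, -0.47, -0.51, -0.23, -0.50 and -0.44 corrected). Ikzf5 did not (log2 fold change 1.74, edgeR adjusted p = 0.077), nor did Scand1 (-0.41, 0.13). Without control 1 the count was 1800, 1526 of them higher.

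Under anti-miR-501-3p, 4 of 28 lists passed camera with a preset correlation and 0 with an estimated correlation, so again only called members are given. All 9 tested mitochondrially encoded genes rose, also adjusted over the list alone, with a median log2 fold change of 0.68, as for mt-Nd1 (0.74), mt-Rnr2 (0.75) and mt-Co1 (0.31). Of 77 nuclear oxidative phosphorylation genes, 43 fell and 1 rose (50 and 1 adjusted over the list alone; median -0.17), with Cox6b1 (-0.26), Uqcrq (-0.36) and Atp5e (-0.31) down and Cycs (0.82) up. Of 78 ribosomal protein genes, 33 fell and 2 rose (35 and 3 adjusted over the list alone; median -0.21), with Rps19 (-0.36) and Rps9 (-0.32) down and Rpl15 (0.56) up. Of 20 GABA receptor and inhibitory postsynapse genes, 12 rose and 2 fell (13 and 2 adjusted over the list alone; median 0.21), with Gabra4 (0.50) and Slc12a2 (0.44) up. These 4 lists passed camera with a preset correlation (adjusted p = 4.4e-06, 3.8e-08, 2.4e-05 and 0.0021, in this order), and none did with an estimated correlation, where camera's adjusted p was 0.640 for each. After GC and length correction, oxidative phosphorylation (median -0.077, camera adjusted p = 5.3e-06) and ribosomal proteins (-0.081, 0.0042) passed, and the mitochondrially encoded genes (-0.027, 0.40) and GABA receptors (0.17 as adjusted p) did not. With an estimated correlation none passed in that setting (smallest camera adjusted p = 0.522). Rps9 lost its call in edgeR without control 1 (adjusted p = 0.0843). Of the lists called under anti-miR-409-5p alone, nuclear-retained transcripts (6 of 15 up, also adjusted over the list alone; median 0.25), the stress response (4 up and 9 down, 4 and 10 adjusted over the list alone; -0.068), lysosome and autophagy (4 and 13, 5 and 15 adjusted over the list alone; -0.095) and glycolysis and hypoxia (3 and 9, 4 and 10 adjusted over the list alone; -0.066) had camera adjusted p = 0.0846, 0.15, 0.0754 and 0.424. Between the anti-miRs, camera's adjusted p was 0.894, 0.78, 0.571 and 2.2e-12 for these 4 lists, and the last of these did not pass with an estimated correlation (0.537) or in fry, which called 0 lists there. Without anti-miR-501-3p replicate 1, camera called nuclear-retained transcripts under anti-miR-501-3p (adjusted p = 0.0481).

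The other 20 lists did not pass camera with a preset correlation in either comparison against control. Counts are given as members up and down, then as up and down adjusted over the list alone, then as the median log2 fold change, for anti-miR-409-5p and after it for anti-miR-501-3p. The members named here do not stand for the balance of their list. Among neuronal lists, the pan-neuronal markers had 6 and 6 (8 and 6; -0.0087), then 7 and 6 (8 and 6; -0.0030), of 20, with the neurofilament gene Nefl (0.22, 0.25), the release protein gene Snap25 (0.32, 0.34) and Dcx (0.39, 0.38) higher. Excitatory neuron markers had 5 and 5 (7 and 5; 0.031), then 9 and 6 (9 and 6; -0.033), of 20. Inhibitory neuron markers had 5 and 2 (6 and 3; 0.050), then 5 and 4 (5 and 4; 0.037), of 22. Glutamate receptor and postsynaptic density genes had 12 and 8 (15 and 10; 0.052), then 13 and 12 (14 and 13; 0.013), of 40, with the scaffold gene Homer1 (0.40, 0.42) higher. Presynaptic genes had 8 and 13 (8 and 16; -0.058), then 7 and 15 (9 and 15; -0.058), of 40. Dendrite, axon and cytoskeleton genes had 9 and 11 (13 and 14; -0.019), then 13 and 15 (14 and 16; -0.025), of 46. Activity-regulated genes had 4 and 10 (4 and 10; -0.12), then 5 and 10 (5 and 11; -0.10), of 42, with the neurotrophin gene Bdnf (0.36, 0.32) among the fewer risers. Voltage-gated ion channel genes had 17 and 4 (19 and 6; 0.077), then 17 and 6 (18 and 12; 0.066), of 40, with Cacnb4 (0.63, 0.68), Kcnd3 (0.31, 0.26) and Kcnq3 (0.29, 0.29) higher in both. The naming rule also took Scn2a (0.31) under anti-miR-409-5p and Cacna2d1 (0.57) under anti-miR-501-3p. It ranks each comparison apart, so this shows no difference between the anti-miRs, and no gene passed between them in the main fit. Among stress and metabolic lists, the interferon response had 1 and 0 (0 and 0; 0.053), then 3 and 0 (0 and 0; 0.11), of 29. The inflammatory and NF-kB list had 2 and 1 (1 and 0; -0.030), then 2 and 1 (2 and 0; -0.0035), of 17, and p53 targets 4 and 2 (4 and 4; -0.0099), then 4 and 6 (4 and 8; -0.098), of 26. Cholesterol synthesis had 5 and 7 (7 and 9; -0.034), then 7 and 5 (8 and 6; 5.2e-05), of 24, and NRF2 targets 2 and 3 (2 and 3; -0.025), then 2 and 3 (1 and 3; -0.067), of 20. Astrocyte markers had 6 and 8 (7 and 10; -0.081), then 4 and 8 (5 and 11; -0.15), of 25, with the glutamate transporter gene Slc1a2 (0.28, 0.25) higher and Acsbg1 (-0.29) lower under anti-miR-501-3p. Microglia and macrophage markers had 1 and 0 (1 and 0; 0.090), then 1 and 0 (0 and 0; 0.28), of 12, the riser being Cd53 (1.09, 0.99). Oligodendrocyte lineage markers had 1 and 0 (0 and 0; -0.099), then 1 and 2 (0 and 0; -0.14), of 20. Endothelial, mural and fibroblast markers had 0 and 4 (0 and 1; -0.081), then 2 and 1 (2 and 1; 0.075), of 26, and proliferation and progenitor markers 3 and 0 (0 and 0; 0.041), then 1 and 1 (0 and 0; -0.16), of 29. The microRNA machinery had 4 and 0 (4 and 0; 0.057), then 5 and 1 (6 and 1; 0.054), of 17, and the host transcripts of the microRNAs and their clusters 1 and 0 (1 and 0; 0.14), then 2 and 0 (2 and 0; 0.19), of 7.

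Camera called some of these 20 lists when a single library was left out. Without control 1 under anti-miR-409-5p, the endothelial, mural and fibroblast markers had a median log2 fold change of -0.21 (camera adjusted p = 0.0021) and the proliferation and progenitor markers 0.22 (0.0044). The proliferation list under anti-miR-501-3p passed camera without control 2 (median -0.36, adjusted p = 4.5e-04) or anti-miR-501-3p replicate 1 (adjusted p = 0.0454). Voltage-gated channels under anti-miR-409-5p passed camera without control 2 (adjusted p = 0.0274) or anti-miR-409-5p replicate 2 (0.0424). Cd53, at 0.590 ± 0.0386 CPM (SD, n = 4) and 0.557 ± 0.0936 (n = 4) against 0.276 ± 0.0123 (n = 2), lost its edgeR call under both anti-miRs without control 1 (adjusted p = 0.118 and 0.142) or control 2 (0.109 and 0.137) and under anti-miR-501-3p without its replicate 3 (0.0782). Acsbg1 lost its edgeR call without control 1 (adjusted p = 0.0625). Signs differed under anti-miR-409-5p for the pan-neuronal list (median -0.0087, mean 0.051, test up), the cytoskeleton list (median -0.019, mean 0.021, test down), p53 targets (median -0.0099, mean -0.022, test up) and oligodendrocyte markers (median -0.099, mean -0.049, test up). They differed under anti-miR-501-3p for the pan-neuronal (median -0.0030, mean 0.065, test up), excitatory (-0.033, 0.089, up), presynaptic (-0.058, 0.0022, down), cytoskeleton (-0.025, 0.017, down) and inflammatory (-0.0035, -0.031, up) lists. With GC and length corrected and a preset correlation, camera called the pan-neuronal list (medians 0.069 and 0.082, adjusted p = 0.0073 and 0.0027) and voltage-gated channels (0.036 and 0.040, adjusted p = 0.0027 and 0.0027) up under both anti-miRs. It also called inhibitory markers up under anti-miR-409-5p (0.065, camera adjusted p = 0.026). Under anti-miR-501-3p it called excitatory (0.060, camera adjusted p = 0.024) and microglia markers (0.32, 0.029) up and proliferation markers (-0.20, 0.040) down. No list passed in this setting with an estimated correlation (smallest camera adjusted p = 0.656 and 0.522). Upper-quartile and total-count scaling turned the medians of excitatory markers under anti-miR-409-5p and of inhibitory markers, glutamate receptors and cholesterol synthesis under anti-miR-501-3p below 0. In the GC and length corrected setting, Homer1 had -0.19 and -0.26 (edgeR adjusted p = 0.0065 and 3.4e-04). Under anti-miR-501-3p in that setting, Dcx had -0.0051 and Bdnf -0.039, and neither passed (edgeR adjusted p = 0.961 and 0.640).

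The same transcripts moved alike under both anti-miRs. Gmfb, which encodes a glia maturation factor, was 1.48-fold and 1.55-fold higher than in control, the glycosylation enzyme gene C1galt1 1.65-fold and 1.76-fold, the dermatan sulfate epimerase-like gene Dsel 1.55-fold and 1.62-fold, and the zinc finger genes Zfp994 and Zfp944 2.22-fold and 2.26-fold, and 2.17-fold and 2.23-fold. In log2 units these were 0.56 ± 0.05 (SE) and 0.63 ± 0.05 for Gmfb, 0.72 ± 0.07 and 0.82 ± 0.07 for C1galt1, 0.63 ± 0.06 and 0.70 ± 0.06 for Dsel, 1.15 ± 0.10 and 1.18 ± 0.10 for Zfp994, and 1.12 ± 0.10 and 1.16 ± 0.10 for Zfp944. The larger edgeR adjusted p of the pair was 3.9e-06 for Gmfb, 9.2e-06 for C1galt1, 8.9e-06 for Dsel, 6.65e-06 for Zfp994 and 8.9e-06 for Zfp944, and these 5 also passed after GC and length correction, whereas mt-Tc, the gene of smallest p called alike, did not (edgeR adjusted p = 0.159 and 0.105). Corrected log2 fold changes were smaller, at 0.16 and 0.16 for Gmfb, 0.32 and 0.38 for C1galt1 and 0.30 and 0.33 for Dsel. They were 0.64 and 0.59 for Zfp994, 0.67 and 0.64 for Zfp944 and 1.00 and 1.08 for mt-Tc. In both comparisons 2434 genes were higher and 1726 lower, with 0 called in opposite directions, while independent lists of these sizes would share 464 and 318. Across genes, which are not independent replicates, the Pearson correlation of the fold changes was 0.870 and their covariance 0.0857. In 40 simulations of unchanged groups against the same pair of controls, the correlation averaged 0.669 (0.647 to 0.694) and the covariance 0.0273 (0.0251 to 0.0304). These simulations drew genes independently, so they hold no shift that moves many genes together, such as a shift along GC content. The controls could not be divided so that each comparison kept a pair of its own, so part of the excess may come from the shared controls. With control 1 for anti-miR-409-5p and control 2 for anti-miR-501-3p the correlation was 0.525 and the covariance 0.0669, and the reverse gave 0.443 and 0.0589. The comparisons share no control library in these settings, so the simulated values, drawn with both controls shared, are no reference for them. Unchanged groups with separate controls were not simulated. Corrected for GC and length, the covariance was 0.0391, with 470 genes higher and 289 lower in both. The deposited comparison tables, made from the same libraries and therefore not independent evidence, called 3601 and 4488 genes, of which 3511 and 4422 were called here too, all in the same direction.

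Genes with a site for the seed of the silenced microRNA in their 3' UTR were slightly higher relative to other genes. Of 14211 genes with a searched 3' UTR, 1400 held a miR-409-5p site, and their median log2 fold change under anti-miR-409-5p was 0.069 against -0.033 for the rest, a difference of 0.10. Called risers with a site included the growth factor gene Fgf7 (1.27), Meioc (1.27), Cd53 (1.09), Pi15 (1.08) and Vma21, an assembly factor gene of the vacuolar proton pump (1.00). A miR-501-3p site was held by 1851 genes, with medians of 0.080 against -0.040 under anti-miR-501-3p and a difference of 0.12, and called risers with a site included Ikzf5, Lypla1, Pi15 (1.19), the ubiquitin-conjugating factor gene Ube2v2 (1.11) and the fucosyltransferase gene Fut9 (1.08). The camera p was 4.5e-06 for miR-409-5p and 3.1e-06 for miR-501-3p with a preset correlation, and the p was 0.0633 and 0.0537 with an estimated correlation. The differences exceeded those of 93 and 97 of 100 heptamers with the same bases in another order. Those heptamers had median differences of 0.071 and 0.068 themselves. All lay above 0, from 0.0045 to 0.14 under anti-miR-409-5p and from 0.019 to 0.13 under anti-miR-501-3p. The seed of the other microRNA gave differences of 0.11 in each comparison. With the trend on UTR length and expression removed the differences were 0.019 and 0.025. The p of cameraPR, camera for ranked values, was 0.446 and 0.240 in that setting with a preset correlation. With GC and length correction the differences were 0.0065 and 0.0061 and exceeded 60 and 71 of the 100 heptamers. Vma21 under anti-miR-409-5p and Ube2v2, Fut9 and Lypla1 under anti-miR-501-3p still passed edgeR's test. Their corrected log2 fold changes were smaller, at 0.43, 0.26, 0.22 and 1.19. Meioc, Fgf7, Cd53 and Pi15 under anti-miR-409-5p lost their edgeR call without control 1 (adjusted p = 0.355, 0.129, 0.118 and 0.228), as did Pi15 under anti-miR-501-3p (0.139). Fgf7 also ended without control 2 (edgeR adjusted p = 0.232), anti-miR-409-5p replicate 2 (0.0626) or 3 (0.0982) or anti-miR-501-3p replicate 2 (0.0508) or 3 (0.0511), and Meioc without anti-miR-409-5p replicate 3 (0.0799) or 4 (0.0678). In the direct comparison of the anti-miRs, miR-409-5p site genes differed from the rest by -0.0055 and miR-501-3p site genes by -0.0075, passing 11 and 95 of 100 heptamers in the direction that release of targets would give.

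The direct comparison asked whether silencing miR-409-5p and miR-501-3p affects neurons differently. Levels were close, and the genes of smallest p, none of which passed, included Fn1, Rgs11, Bnip3 and Hebp1. The fibronectin gene Fn1 (mm10 chromosome 1, 71585520 to 71653200) had 53.7 ± 2.02 CPM (SD, n = 4) under anti-miR-409-5p and 69.1 ± 3.24 (n = 4) under anti-miR-501-3p. Rgs11, a regulator of G protein signalling (chromosome 17, 26202951 to 26211324), had 77.0 ± 3.36 and 89.2 ± 2.25 CPM, and the hypoxia-induced mitophagy gene Bnip3 48.9 ± 0.934 and 59.8 ± 5.22. In log2 units the differences were -0.36 ± 0.06 (SE) for Fn1, -0.21 ± 0.04 for Rgs11, -0.29 ± 0.05 for Bnip3 and -0.22 ± 0.05 for the heme-binding gene Hebp1 (edgeR adjusted p = 0.154 for the first 3 and 0.550 for Hebp1). In edgeR's quasi-likelihood test 0 of 16884 genes passed, with 992 at an unadjusted p under 0.05, limma's voom called 0 (1549 unadjusted), and DESeq2 called 3, Fn1, Rgs11 and Bnip3 (628 unadjusted). The 3 genes had the same sign in all these tests, and Fn1 passed edgeR's test without control 1 (adjusted p = 0.00245) or control 2 (0.00246). With the replicate number as a block, edgeR called 252 genes, 98 higher and 154 lower under anti-miR-409-5p (2218 unadjusted). These included Fn1 (edgeR adjusted p = 0.019), Rgs11 (2.0e-04), Bnip3 (0.0012) and Hebp1 (0.0023). The pairing check passed over genes with a mean log2 CPM above 1, but not over all tested genes or after GC and length correction.

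Between the anti-miRs 6 of 28 lists passed camera with a preset correlation, 0 with an estimated correlation and 0 in fry, so no change of a group is claimed. Of 30 glycolysis and hypoxia genes 0 passed over all genes and 17 were lower adjusted over the list alone, with a median log2 difference of -0.11, and Pdk1 (-0.18), which restrains pyruvate oxidation, Eno2 (-0.13) and Gpi1 (-0.13) passed edgeR's test with the block (adjusted p = 0.0057, 0.0049 and 0.035). Of 26 endothelial, mural and fibroblast markers 0 passed over all genes and 3 were lower adjusted over the list alone (median -0.22), and the receptor genes Kdr (-0.30) and Pdgfrb (-0.22) passed edgeR's test with the block (adjusted p = 0.0057 and 0.031). The proliferation and progenitor markers had 0 of 29 over all genes and 0 adjusted over the list alone (median 0.23), and Aurkb (0.38), Rrm2 (0.30) and Ccnb1 (0.54), genes of mitosis and nucleotide synthesis, passed edgeR's test with the block (adjusted p = 0.043, 0.010 and 0.042). Oligodendrocyte (median 0.14) and astrocyte (0.056) markers and cholesterol synthesis genes (-0.043) also had 0 members over all genes and 0 adjusted over the list alone. In the block fit, the sterol synthesis enzyme gene Hmgcs1 (-0.13) passed edgeR's test (adjusted p = 0.0064) and Msmo1 (-0.093) did not (0.054). With a preset correlation, camera's adjusted p was 2.2e-12 for glycolysis and hypoxia, 3.0e-07 for proliferation, 2.7e-04 for endothelial, mural and fibroblast markers, 0.0021 for cholesterol synthesis, 0.0057 for oligodendrocyte and 0.0212 for astrocyte markers. With an estimated correlation none of these 6 lists passed, with camera adjusted p = 0.537 for glycolysis and hypoxia, endothelial and astrocyte markers, 0.632 for proliferation and 0.682 for cholesterol synthesis and oligodendrocyte markers. The glycolysis and hypoxia score of anti-miR-501-3p replicate 1 (6.95 log2 CPM) lay above those of the other libraries of that group (6.79 to 6.81), and without it the median was -0.081 (camera adjusted p = 1.7e-06). Camera's call ended for cholesterol synthesis without anti-miR-409-5p replicate 4 (adjusted p = 0.0735) or anti-miR-501-3p replicate 1 (0.142), and for oligodendrocyte markers without anti-miR-409-5p replicate 4 (0.0961) or anti-miR-501-3p replicate 2 (0.0541) or 3 (0.192). For astrocyte markers it ended without anti-miR-409-5p replicate 2 (camera adjusted p = 0.118) or 4 (0.0740) or anti-miR-501-3p replicate 2 (0.0726) or 3 (0.12).

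The other 22 lists did not pass camera between the anti-miRs, and none of their members passed over all genes. Their medians lay within 0.06 log2 of 0 except for microglia and macrophage markers (-0.14, camera adjusted p = 0.185). Adjusted over the list alone, the pan-neuronal list had 1 lower member and the others 0. P53 targets (median 0.051, camera adjusted p = 0.0901) passed with the replicate block (0.043, and 0.429 with an estimated correlation) or without anti-miR-501-3p replicate 1 (0.0206). The interferon response (median -0.056, camera adjusted p = 0.0869) passed without control 1 (0.0298), control 2 (0.0291) or anti-miR-501-3p replicate 1 (0.0359) or 4 (0.0112). Mitochondrially encoded genes (median -0.045) passed camera without anti-miR-501-3p replicate 1 (adjusted p = 0.0206). They passed in the opposite direction with GC and length correction (median 0.073, camera adjusted p = 0.0016, and 0.449 with an estimated correlation) and with the block added to it (0.073, 0.0022). Ribosomal proteins (0.019) passed camera without anti-miR-409-5p replicate 4 (adjusted p = 0.0024) or anti-miR-501-3p replicate 1 (0.0359), and oxidative phosphorylation (0.0072) without anti-miR-409-5p replicate 4 (0.0188). The nuclear-retained list differed in sign between median (-0.023) and mean (0.046, test up), as did oxidative phosphorylation (median 0.0072, mean -7.3e-04, test up) and NRF2 targets (median 1.6e-04, mean -0.015, test down).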

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

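The test of the blocked count between the anti-miRs, the floor set for marker lists, the bound under which release would be excluded and all values with GC and length correction were chosen after the results were seen.

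Of 300 groups of 4 libraries examined for a library whose gap to its nearest neighbour takes most of the group's range (Dixon's test, 95% critical value), 17 held one: 11 of 236 gene groups, 6 of 56 list scores and 0 of 8 library measures, where chance gives about 1 in 20. Anti-miR-501-3p replicate 1 stood apart, toward the control level, for Cacna2d1 (gap share 0.853), Lypla1 (0.884), Meg3 (0.984), Rian (0.832), Rplp0 (0.869), Snap25 (0.932), Snhg14 (0.912) and Ube2v2 (0.943). Meg3, for example, had 11.45 log2 CPM there against 11.77 to 11.78 in the other 3 libraries. The same library stood apart in the scores of pan-neuronal markers (0.833), glycolysis and hypoxia (0.896) and astrocyte markers (0.855). It also had the lowest mitochondrial share of its group (3.33%) and the GC slope nearest to control (0.0078). Anti-miR-409-5p replicate 4 stood apart in the scores of glutamate receptors (0.892) and presynaptic genes (0.941), and anti-miR-409-5p replicate 1 in the stress response score (0.871) and for mt-Ta (0.901; 3.49 against 4.07 to 4.13 log2 CPM). Single genes elsewhere were Cox16 in anti-miR-501-3p replicate 4 (0.964) and Zfp995 in anti-miR-409-5p replicate 2 (0.944).

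Both anti-miRs shared changes against control that followed transcript GC content, and after removal of the trend on GC content and length, at most 15.1% of the calls in either comparison kept their direction and passed in edgeR, as the median absolute log2 fold change of called genes dropped from 0.25 and 0.26 (SE 0.06) to 0.07 and 0.08 (SE 0.047 and 0.048), so a GC-linked difference between the 2 control and 8 anti-miR libraries may account for most of them. A different share of glial and other non-neuronal cells stays open: the values met the bound set against it, but not by more than their spread. Under anti-miR-409-5p the 4 glial and vascular medians lay within 0.1 of 0, with oligodendrocyte markers at -0.099, and under anti-miR-501-3p the endothelial list (0.075) lay opposite the astrocyte list (-0.15), yet its scores overlapped (3.09 and 3.43 log2 CPM in control, 3.25 to 3.47 under anti-miR-501-3p), and the 1 list opposite in both, microglia markers, lay near the floor (0.52 to 0.83). Gene-by-gene sampling noise of the 2 shared controls was argued against as the whole source, with a covariance of 0.0857 against at most 0.0304 in simulated unchanged groups. The simulated genes were drawn independently, so a shift of the controls across many genes together, as along GC content, stays open. Whether the GC trend arose in library preparation or in the cells stays open, since it runs with the treatment and the labels give no batch, and a shared response to an anti-miR cargo was not tested against another control.

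A release of seed-site transcripts could raise genes with a site. For miR-409-5p the site genes exceeded 93 of 100 reordered heptamers against control (median heptamer difference 0.071), short of the 95 required. They passed 11 of 100 in the predicted direction between the anti-miRs. Their difference was 0.10 against control but -0.0055 between the anti-miRs, where the heptamers ran from -0.014 to 0.014. These values argue against release by its own anti-miR as the source of the whole difference, and leave a smaller release open. For miR-501-3p the site genes exceeded 97 of 100 against control (median heptamer difference 0.068) and passed 95 of 100 between the anti-miRs. After GC and length correction these were 71 and 87 of 100, and the seed of the other microRNA gave a like difference against control (0.11), and removal of the trend on UTR length and expression left differences of 0.019 for miR-409-5p and 0.025 for miR-501-3p. The miR-501-3p site genes differed by 0.12 against control but by -0.0075 between the anti-miRs, where the heptamers ran from -0.011 to 0.0088. This likewise argues against release by its own anti-miR as the source of the whole difference. For both microRNAs a smaller release cannot be told apart from the trends on GC content, UTR length and expression.

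Between the anti-miRs, the count of 0 genes in edgeR (992 at an unadjusted p under 0.05, DESeq2 3, limma's voom 0) is reached by all 35 of 35 splits of the 8 libraries whatever the data, so the splits decide nothing about it. The highest other split had 91 genes and set replicates 1 and 2 of both groups against replicates 3 and 4. It follows the GC slope as well, which ran from -0.088 to 0.038 in the former and from -0.131 to -0.092 in the latter. A structure along the replicate numbers and one along GC content cannot be told apart in this split. With the replicate block the real split gave 252 genes and the highest of the other splits that part all 4 pairs gave 0. That is 1 of 8 splits, and 8 splits are too few for a share under 0.05.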

How the results depend on the processing

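GC and length correction, with or without the replicate block, was chosen for its tests after the results were seen, and the other alternatives were not.

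Both counts against control stayed within 1.5 times under RLE, upper-quartile and total-count scaling, both filters, DESeq2, limma's voom, a fit of the compared groups alone and the replicate block (4206 to 5402 and 4928 to 6231). They became 831 (743 higher, 88 lower) and 592 (567 higher, 25 lower) with a surrogate variable, 894 and 1349 with GC and length correction and 979 and 1450 with that correction and the block. Between the anti-miRs the count of 0 became 42 with no filter, 3 with DESeq2, 1 with those groups alone, 11 with a surrogate variable, 2 with GC and length correction, 252 with the replicate block and 183 with both. Leaving out a library in turn gave 1302 to 5111, 1800 to 6075 and 0 to 1 genes, and only control 1 moved a count against control by over 1.5 times (1302 and 1800). Lists passing were 0, 0 and 0 with an estimated correlation and 13, 11 and 0 with fry. For anti-miR-501-3p they were 7 with no filter, 7 with GC and length correction and 9 with it and the block, and for anti-miR-409-5p 5 and 4. Lists ran from 7 to 10, 4 to 6 and 4 to 9 without a library in turn. The seed-site differences became 0.019 and 0.025 with the trend on UTR length and expression removed and 0.0065 and 0.0061 with GC and length correction, and ran from 0.089 to 0.13 and 0.10 to 0.13 without a library in turn. The cause was not tested for these changes, except that a left-out library leaves fewer samples. The correlation of anti-miR effects was 0.754 with GC and length correction, 0.934 with the stricter filter and 0.853 with the block.

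With GC and length correction signs reversed as follows where the value passed with or without it, and the cause was not tested. Under anti-miR-409-5p these were Rian (-0.43), mt-Co1 (-0.011), Rps15 (0.022), Lamp2 (-0.082), Snhg14 (-0.0013), Homer1 (-0.19) and the pan-neuronal median (0.069). Under anti-miR-501-3p they were Rian (-0.51), mt-Rnr2 (-0.017), mt-Co1 (-0.067), Dcx (-0.0051), Homer1 (-0.26), Bdnf (-0.039) and the medians of the pan-neuronal (0.082), excitatory (0.060) and mitochondrially encoded (-0.027) lists, and between the anti-miRs the last was 0.073. With the replicate block added they were Rian (-0.36), Lamp2 (-0.048), Snhg14 (-0.071), Homer1 (-0.15) and pan-neuronal (0.043) under anti-miR-409-5p, Rian (-0.44), mt-Co1 (-0.036), Homer1 (-0.22), Bdnf (-0.043), pan-neuronal (0.056) and mitochondrially encoded (-0.036) under anti-miR-501-3p, and mitochondrially encoded (0.073) between them. Of named genes that passed in neither fit, Clcn5 under anti-miR-409-5p (-0.074) and Rian between the anti-miRs (0.081) also turned. Of 145 calls of named genes, GC and length correction ended 55, kept 86 in direction and turned 4, and a surrogate variable ended 69. The replicate block alone brought 17 past the threshold, all between the anti-miRs, and ended 5 (Gt(ROSA)26Sor under anti-miR-409-5p, and Cd53 and Cox16 under both). The call of the stress response list under anti-miR-409-5p ended with RLE scaling (camera adjusted p = 0.0515) and that of the astrocyte list between the anti-miRs with no filter (0.0534). Lysosome genes under anti-miR-501-3p passed camera with upper-quartile (adjusted p = 0.034) or total-count scaling (0.030) and with no filter (0.027), as did, with no filter, voltage-gated channels under anti-miR-409-5p (0.010) and anti-miR-501-3p (0.039) and nuclear-retained transcripts under anti-miR-501-3p (0.0147). The replicate block called the proliferation list under anti-miR-501-3p (camera adjusted p = 0.023) and p53 targets between the anti-miRs (0.043), neither of which passed with an estimated correlation in that fit (camera adjusted p = 0.672 and 0.429), and changed no other list call. Against control 2 pairs share numbers, with correlations of 0.293 and 0.0423 for anti-miR-409-5p and 0.359 and 0.211 for anti-miR-501-3p, and the block gave 4886 and 5729 genes. Between the anti-miRs, anti-miR-409-5p replicate 3 did not correlate best with its own number over the 12832 genes with a mean log2 CPM above 1. Over all 16884 tested genes it did. Depth limits low genes: 3 counts equal 0.0935 to 0.135 CPM, and genes such as Cd53, Fgf7 and Zfp820 lie within a few times that level in control.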

Other observations

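The genes of this part were chosen after their values were seen, and so were the tests with GC and length correction.

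A run of neighbouring zinc finger genes on chromosome 17 (mm10, from Zfp820 at 21816885 to Zfp758 at 22377281) was higher under both anti-miRs. Of 8 tested genes, 7 rose in both comparisons with control in edgeR's test (Zfp820, Zfp995, Zfp942, Zfp943, Zfp994, Zfp944 and Zfp758), and Zfp947 did not pass (edgeR adjusted p = 0.174 and 0.143). Zfp942 went from 15.6 ± 2.06 CPM (SD, n = 2) to 32.4 ± 2.57 (n = 4) and 35.2 ± 3.87 (n = 4), and the median log2 fold change of the 8 genes was 1.08 and 1.16. After GC and length correction the same 7 passed in both comparisons, with medians of 0.57 and 0.57. Among 359 other tested Zfp genes, 113 rose and 21 fell under anti-miR-409-5p and 115 and 32 under anti-miR-501-3p, with medians of 0.12 and 0.12, and after the correction 4 and 4, and 5 and 11, with medians of 0.0041 and -0.0047. The transcripts of the 8 neighbours hold 35.4% to 39.6% GC and those of the other Zfp genes 34.4% to 68.7%. The sets are thus not matched in GC content. Tested genes under 38% GC with a mean log2 CPM above 1 had medians of 0.61 and 0.71 before the correction. How reads shared between related Zfp genes were counted is not stated, so single members are uncertain.

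Several genes kept a large change after GC and length correction, or showed a larger change than before it. The correction made 58 of the original calls under anti-miR-409-5p and 110 under anti-miR-501-3p pass in the opposite direction. A larger change after it may therefore come from the correction itself. Marcks, which encodes a membrane-bound substrate of protein kinase C, rose from 189 ± 10.4 CPM (n = 2) to 332 ± 34.8 (n = 4) and 336 ± 6.76 (n = 4), log2 0.81 ± 0.08 (SE) and 0.83 ± 0.08, and 0.68 and 0.69 after correction (edgeR adjusted p = 0.0011 and 6.7e-04). The synaptic organizer gene C1ql3 rose by 0.59 ± 0.09 and 0.63 ± 0.09 (0.68 and 0.73 corrected, edgeR adjusted p = 3.8e-05 and 1.0e-05), and the vesicular monoamine transporter gene Slc18a2 by 1.04 ± 0.16 and 1.07 ± 0.16 (0.83 and 0.84 corrected, edgeR adjusted p = 7.1e-04 and 4.0e-04). The cytochrome c oxidase genes Cox7c (-0.46 ± 0.12 and -0.30 ± 0.12) and Cox16 (-0.48 ± 0.16 and -0.47 ± 0.16) were lower, with corrected values of -0.86 and -0.78, and -0.95 and -1.01 (edgeR adjusted p = 4.2e-04, 5.5e-04, 0.0011 and 4.1e-04). Without correction Cox7c did not pass under anti-miR-501-3p (edgeR adjusted p = 0.0676), except without its replicate 1 (0.0397) or 2 (0.0371), and under anti-miR-409-5p it ended without control 1 (0.166). Cox16 ended without control 1 (edgeR adjusted p = 0.266 and 0.263), without control 2 (0.0597 and 0.0538), without anti-miR-409-5p replicate 3 (0.0580) or 4 (0.0800) under anti-miR-409-5p and without anti-miR-501-3p replicate 4 (0.0830) under anti-miR-501-3p.

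Between the anti-miRs, the blocked edgeR fit called Arrdc3 and the astrocytic potassium channel gene Kcnj10 (adjusted p = 5.2e-06 and 9.3e-06). It also called the lactate dehydrogenase gene Ldha and the transporter gene Slc16a6 (adjusted p = 2.5e-04 and 1.5e-04). In the fit without the block, the log2 differences were -0.24 ± 0.11 (SE), 0.22 ± 0.09, -0.16 ± 0.04 and -0.30 ± 0.11, in this order. There edgeR's adjusted p was 0.848, 0.845, 0.741 and 0.833.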
